A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

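RNA was measured in 16 samples of budding yeast on Agilent 2-colour expression arrays. The samples were 4 W303 strains, each taken before salt (0 min) and 10, 20 and 30 min after NaCl was added to 0.4 M in rich medium (YPD) at 30 °C. By their labelled genotypes the strains were wild type (WT), a strain without the stress transcription factor genes MSN2 and MSN4 (msn24), a strain without CDC55 (cdc55), which encodes a regulatory subunit of the phosphatase PP2A, and a strain without all of these (cdc55 msn24). Each strain and time had 1 sample, so no group had a replicate. A WT sample (Cy3) shared each of 4 arrays with the msn24 sample of the same time (Cy5), and a cdc55 sample (Cy3) shared each of the other 4 arrays with the cdc55 msn24 sample (Cy5). Dyes were not swapped. All 8 arrays lay on 1 slide with 1 scan time, so slide and scan were not batches that could be tested.

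Per the labels' protocols, total RNA was extracted with glass beads and phenol and labelled with a 2-colour amplification kit. Per the file headers, spots were quantified with Agilent Feature Extraction 10.7.3.1, the deposited scanner values are spot intensities on a linear scale, and the array was annotated on the sacCer1 build. The scanner tables held 8 scans, each deposited with both of its samples, and every scan was used once. They gave median spot signals, not the mean signals that the plan had named, so median signal and median local background were used. The deposited series matrix holds intensities too. Its columns matched Feature Extraction's processed signal of each sample's own dye within 0.6% for 100% of values, so they are linear, uncentred, dye-normalized within an array and not scaled between arrays. Their column medians ran from 278 to 595.

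Signals were background-corrected with normexp (offset 50), normalized within arrays by loess with control spots at weight 0, and between arrays by Aquantile, with limma 3.58.1 in R 4.3.3. Spots marked as outliers were left out. Each of the 6256 gene probes was printed as 2 spots, which were averaged on the log2 scale, and probes were averaged over the 27 genes that had several. Genes were tested if a spot of the probe was well above background in at least 4 of the 16 samples and every sample had a value, which left 5468 genes. No probe was saturated (0 of the 6256). Names were taken from a RefSeq gene table of assembly R64, which matched 5740 of the 6228 names on the array. The remaining 488 kept the array's name. Because the builds differ, no coordinates are given.

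Median spot signal was 344 to 669 in Cy3 and 286 to 1089 in Cy5. Cy3 carried more haze, with negative control spots at 140.5 to 189 against 65 to 71 in Cy5, and 52.8% to 75.7% of Cy3 spots stood well above background against 81.4% to 89.9% of Cy5 spots. Pairs of samples correlated at 0.834 to 0.988 across genes. Duplicate spots differed by an SD of 0.15 to 0.48 log2 within a sample. On some arrays the spots of a probe disagreed by over 2-fold in both dyes, relative to the other arrays. This held for 374 probes on the array of WT and msn24 at 0 min and 287 on that of cdc55 and cdc55 msn24 at 0 min, and for 4 to 116 on the others. The 607 tested genes with such discordant spots stayed in the tests, and their values are named as such. The number of arrays limits the precision.

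With 1 sample per group, a model needs strains or times to stand in for repeats. The salt response over the strains was tested with limma as the mean of 10, 20 and 30 min minus 0 min, with strain and time as terms (9 residual degrees of freedom). Strain differences in level used the same model. Differences between strains in the salt response were tested as interactions of strain with salt (6 residual degrees of freedom), in which a gene-specific dye bias cancels. The array entered as a random block, with a correlation of 0.379 in the first model and 0.361 in the second. P-values were adjusted by Benjamini-Hochberg, with 0.05 as the threshold. They measure the spread between strains and times, part of which can be technical, and the lone 0 min sample of a strain is assumed to vary like the rest. Fold changes per strain and time were described without a test.

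Before the data were examined, 24 gene lists, the rule for named genes, the models and the alternatives were fixed. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. Lists could share members, as most of the trehalose and glycogen list did with the STRE list. None of the camera calls of these lists (0 in each comparison) held with an estimated correlation. A list's median change in 1 strain at 1 time was placed among 10000 random lists of its size, matched on mean expression in 20 bins. Genes named are the deleted and marker genes, 11 anchor genes of the stress and cell cycle literature, for salt the 12 largest rises and 12 largest falls past the threshold that went the same way in all 4 strains, for other comparisons up to 10 highest and 10 lowest, up to 4 members with the largest change of a list, and the 5 highest and 5 lowest at 0 min among genes well above background in both samples. Dubious reading frames are named only as such. A gene that this rule would name is not reported here. A gene not well above background in the dimmer group has only a lower bound for its fold, computed against the lowest signal that stood well above background.

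Alternatives were Feature Extraction's processed signals, quantile normalization over 16 channels, scaling on the 75th percentile, no filter or a filter on all 16 samples, no array block, the brightest probe, the series matrix, each time or strain left out, levels under salt only, and fold thresholds of 1.5 and 3. Chosen after seeing the data were: leaving out the genes with discordant spots, dropping the lower spot of such a pair, starting from background-subtracted signals, testing the difference of the cdc55 level effects, and 3 further gene lists. The code was tested on simulated data of 5468 genes with 200 changed genes. In the salt model 93% of changes of 1 log2 and 100% of changes of 2 log2 were recovered, with 16 unchanged genes called. In the cdc55 interaction 43% and 95% were recovered, with 10 unchanged genes called. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.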

Results

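Transcript levels of 5468 genes were measured in 16 yeast samples, 1 for each of 4 strains at 0, 10, 20 and 30 min in 0.4 M NaCl, on 8 arrays. The comparisons ask which genes respond to hyperosmotic salt, which part of the response needs the stress transcription factors Msn2 and Msn4, and how it changes without Cdc55, a regulatory subunit of the phosphatase PP2A. Median spot signal per sample ran from 286 to 1089. No strain and time was replicated, so each ± given for a strain is the SD over the 3 salt times. Each fitted log2 change carries its SE, and limma with Benjamini-Hochberg adjustment was the test for genes.

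The transcript probes matched the strain labels in part. MSN2, which encodes a stress transcription factor, was at least 8.19-fold higher in WT than in msn24 and at least 8.76-fold higher in cdc55 than in cdc55 msn24, and its probe was not well above background in any of the 4 msn24 and 4 cdc55 msn24 samples. The CDC55 probe, whose spots were discordant, was measured 1.22-fold higher in WT than in cdc55 (log2 difference 0.28 ± 0.57 SD over 4 times), where it stood well above background in 2 of 4 samples. Its log2 signal was lower in WT at 0 min (7.50 against 8.04) and higher at 10, 20 and 30 min (8.69, 9.22 and 9.05 against 8.28, 8.45 and 8.56). It was 1.10-fold higher in msn24 than in cdc55 msn24 (0.14 ± 0.30), where it stood above background in 4 of 4, so it does not check the cdc55 label. Nor does the MSN4 probe check the msn24 label, since MSN4 was at least 1.67-fold higher in msn24 than in WT and at least 2.05-fold higher in cdc55 msn24 than in cdc55. Among the auxotrophic marker genes, the histidine gene HIS3 was at least 5.01-fold and the tryptophan gene TRP1 at least 5.51-fold higher in msn24 than in WT. In cdc55 msn24 TRP1 was 3.37-fold and HIS3 at least 3.70-fold higher than in cdc55. The adenine gene ADE2, whose spots were discordant, was 7.69-fold higher in cdc55 than in WT and 2.73-fold higher in cdc55 msn24 than in msn24. Mean log2 signals in WT, msn24, cdc55 and cdc55 msn24 were 11.62, 11.80, 12.33 and 11.79 for URA3 and 11.97, 11.94, 12.34 and 12.24 for LEU2. They were 8.21, 8.60, 8.60 and 8.55 for LYS2, and 9.85, 10.00, 9.69 and 10.34 for CAN1.

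Mating type differed along with the msn24 label. MF(ALPHA)1, the gene of the alpha-factor precursor, was at least 35.6-fold higher in msn24 than in WT and at least 41.9-fold higher in cdc55 msn24 than in cdc55. STE6, the a-factor exporter of a cells, was 5.78-fold higher in WT than in msn24 and 10.9-fold higher in cdc55 than in cdc55 msn24, and the a-cell protease gene BAR1 was at least 3.25-fold higher in WT than in msn24. Strains with and without MSN2 therefore differed in mating type and in dye (Cy3 or Cy5) as well as in MSN2.

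Over the 4 strains together, salt raised 21 of 33 genes of the Hog1 kinase programme and 35 of 64 stress genes with STRE elements and lowered 89 of 106 ribosome biogenesis genes. HSP12, which encodes a small heat shock protein at membranes, rose most, 30.2-fold (log2 4.92 ± 0.14, adjusted p = 1.84e-10), and was 31.3-fold above 0 min in WT, 25.8-fold in msn24, 28.4-fold in cdc55 and 36.3-fold in cdc55 msn24. The glycerol-phosphate phosphatase gene GPP2 rose by 3.93 ± 0.12 (adjusted p = 3.23e-10) and was 12.2-fold (WT) to 19.4-fold (cdc55 msn24) above 0 min in the strains. GPD1, which makes glycerol 3-phosphate, rose by 2.38 (adjusted p = 1.02e-06), with folds of 5.26, 6.83, 3.55 and 5.76 in WT, msn24, cdc55 and cdc55 msn24. STL1, the glycerol importer, rose (adjusted p = 3.41e-05) from a level not above background at 0 min, at least 7.13-fold in WT, 7.47-fold in msn24 and 13.1-fold in cdc55 msn24, with no bound in cdc55. Other large rises were those of MPC3, a mitochondrial pyruvate carrier subunit (4.13), RTC3 (3.93), NQM1, a transaldolase (3.40), and CTT1, the cytosolic catalase (3.32). Behind them came YHR033W (2.99), ALD4, a mitochondrial aldehyde dehydrogenase (2.91), FMP45 (2.91, discordant spots), THI4 of thiamine synthesis (2.82) and PHM7 (2.75). The adjusted p of these 9 genes ran from 1.39e-07 to 0.00045, but RTC3 was not above background at 0 min in msn24 and cdc55, nor FMP45 and PHM7 in WT and cdc55, so the sizes of their rises are not known. The sodium pump gene ENA1 rose by 1.23 (adjusted p = 9.78e-05) and GRE2, a stress reductase with discordant spots, by 2.27 (adjusted p = 1.67e-05).

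The largest falls were those of ALB1 (-2.46 ± 0.29, adjusted p = 3.06e-05), AAH1, the adenine deaminase (-2.17), and the ribosome assembly genes NOP4 (-2.16), RLP7 (-2.15), NOP15 (-2.10), SYO1 (-2.04) and RRS1 (-1.95). INA1 (-2.11), HPT1 of purine salvage (-2.09, discordant spots), HSP30 (-2.09), and the ribosomal protein genes RPL22B (-2.08) and RPS9A (-1.98) completed the 12 largest, all with adjusted p of 0.000778 or lower. Each of these 24 genes changed the same way in 4 of 4 strains, as the rule for naming them required. The cyclin genes CLB2 (-0.55, adjusted p = 0.00326, above background in 9 of 16 samples) and CLN2 (-0.53, adjusted p = 0.000465) fell too. The genes called in the salt response over the strains were 1206 higher and 1402 lower, 1171 and 1372 of them the same way in every strain. Of the called genes 239 higher and 97 lower had discordant spots, out of 607 such genes among the 5468 tested. As 2 strains share each 0 min array, agreement of 4 strains does not rest on 4 independent 0 min measurements. An unadjusted p under 0.05 held for 2960. With the series matrix, which is not scaled between arrays and puts the median change of all genes at -0.29, 575 rose and 2031 fell.

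Stress genes with STRE elements, the binding sites of Msn2 and Msn4, had 35 of 64 members higher and none lower (35 and 0 adjusted over the list alone), a median of 1.17 and a camera adjusted p = 3.19e-10. That p was 0.504 with an estimated correlation. Of the 33 glycerol and osmostress genes of the Hog1 kinase programme, 21 rose and 1 fell (22 and 2 adjusted over the list alone), with a median of 0.60 (adjusted p = 1.84e-07 with camera, adjusted p = 0.244 with an estimated correlation). Among them the hexose transporter gene HXT5 rose (adjusted p = 0.00265), but it was not above background at 0 min in WT and cdc55, so the size of its rise is not known. Of 21 genes of trehalose and glycogen metabolism 5 rose (2 adjusted over the list alone), among them the trehalose synthesis genes TPS2 (1.63), TSL1 (1.58) and TPS1 (1.00). Their median was 0.56 (adjusted p = 0.0262, adjusted p = 0.69 with an estimated correlation). Of 25 iron uptake genes 11 rose and 2 fell (11 and 3 adjusted over the list alone), including the cell wall protein gene FIT1 (1.72, not above background at 0 min in cdc55), the oxidase gene FET3 (1.10) and the metal transporter gene SMF3 (0.94). Their median was 0.33 (adjusted p = 0.00763, adjusted p = 0.489 with an estimated correlation).

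Ribosome biogenesis genes fell, 89 of 106 with none higher (95 lower and 1 higher adjusted over the list alone), by a median of -1.12 (camera adjusted p = 6.81e-17, adjusted p = 0.489 with an estimated correlation). Among 131 ribosomal protein genes, many of which are near-identical pairs whose probes can take signal from each other, 63 fell and 13 rose (66 and 13 adjusted over the list alone). Their median of -0.24 (adjusted p = 0.00115, adjusted p = 0.69 with an estimated correlation) turned to 0.08 with scaling on the 75th percentile. RPL12B (2.36) and RPL41B (1.85) rose, both with discordant spots. Amino acid synthesis genes had 32 of 60 lower and 2 higher (33 and 2 adjusted over the list alone), such as LEU9 (-1.31), ILV1 (-1.27), MET6 (-1.26) and HOM3 (-1.17). Their median was -0.33 (adjusted p = 3.04e-05, adjusted p = 0.489 with an estimated correlation). Phosphate uptake genes had 12 of 18 lower (13 adjusted over the list alone), such as the phosphatase gene PHO12 (-1.54) and the transporter gene PHO84 (-1.29), with a median of -0.49 (adjusted p = 0.000663, adjusted p = 0.489 with an estimated correlation).

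Among the cell cycle lists, of 49 G1/S genes 23 fell and 2 rose (the same counts adjusted over the list alone), including MNN1 (-1.66), the ribonucleotide reductase gene RNR1 (-1.44), the mismatch repair gene MSH6 (-1.05) and the cohesin gene SMC3 (-1.01). Their median was -0.27 (camera adjusted p = 0.000559, adjusted p = 0.489 with an estimated correlation). Of 27 M/G1 genes 15 fell (15 adjusted over the list alone), including the mating-type endonuclease gene HO (-1.59) and its repressor ASH1 (-1.38), with a median of -0.35 (adjusted p = 0.00019, adjusted p = 0.489 with an estimated correlation). G2/M genes had 12 of 26 lower and 2 higher (12 and 2 adjusted over the list alone), among them AIM44 (-1.22), IQG1 (-0.81) and BUD4 (-0.69), genes of the bud neck or bud site, and a median of -0.30 (adjusted p = 0.0405, adjusted p = 0.61 with an estimated correlation). Histone genes had 5 of 10 lower (5 lower and 1 higher adjusted over the list alone), such as HHT1 (-0.67), with a list adjusted p = 0.123.

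Chaperone genes had 13 of 30 higher and 3 lower (13 and 3 adjusted over the list alone), of which SSA4 (2.06), STI1 (1.03) and HSP82 (0.92) had discordant spots. Their median was 0.36 (camera adjusted p = 0.0124, adjusted p = 0.607 with an estimated correlation). The small chaperone gene HSP26 stood at 1.22 (adjusted p = 0.111). Glycolysis genes had 7 of 18 higher and 1 lower (7 and 1 adjusted over the list alone), among them the pyruvate decarboxylase gene PDC5 (1.24), ENO2 (0.96) and TDH2 (0.70). Their median was 0.20 (adjusted p = 0.00763, adjusted p = 0.489 with an estimated correlation). Genes of the PP2A and protein kinase A pathways had 13 of 24 higher and 2 lower (16 and 3 adjusted over the list alone), with the regulatory subunit gene BCY1 (1.14) higher and the GTPase gene RAS1 (-1.03) lower. Their median was 0.30 (adjusted p = 0.00576, adjusted p = 0.489 with an estimated correlation). The other lists did not pass (camera adjusted p from 0.123 to 0.68), and their counts adjusted over the list alone were the same except where given. Oxidative stress genes had 11 of 29 higher and 6 lower, such as MCR1 (1.25) and GRX2 (1.19), and mitochondrial respiration genes had 15 of 47 higher and 7 lower. Hexose transporters had 4 of 14 higher and 2 lower, and ergosterol synthesis genes 6 of 27 higher and 9 lower. Pheromone response genes had 8 of 31 higher and 3 lower (7 and 3 adjusted over the list alone), with a median of -0.01 but a mean of 0.12, and cell wall integrity genes 7 of 35 higher and 5 lower (6 and 5 adjusted over the list alone), with a median of -0.06 but a mean of 0.14. Of 10 mating type genes 1 fell (0 adjusted over the list alone), of the 7 auxotrophic marker genes 4 fell, and of the deleted genes CDC55 passed as higher, with discordant spots.

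The median change of the STRE list, averaged over the salt times, was 2.74 ± 0.31 in WT, 0.50 ± 0.02 in msn24, 0.85 ± 0.18 in cdc55 and 0.57 ± 0.19 in cdc55 msn24, each time above 100% of the 10000 matched random lists. With Feature Extraction's processed signals these medians were 3.18, 1.24, 1.22 and 0.84, so msn24 and cdc55 are not ranked. In single genes, DDR2, a stress gene, was 56.8-fold above 0 min in WT and 1.38-, 3.72- and 2.39-fold in msn24, cdc55 and cdc55 msn24. The trehalose synthase gene TPS1 was 5.25-fold above 0 min in WT and 1.20-, 1.97- and 1.30-fold in the others, and CTT1 19.2-fold against 5.23-, 8.20- and 12.1-fold. The trehalose and glycogen list stood at 1.51 ± 0.31 in WT, 0.08 ± 0.21 in msn24, 0.27 ± 0.08 in cdc55 and 0.16 ± 0.14 in cdc55 msn24, with negative values in msn24 under 75th percentile scaling (-0.46) and in cdc55 msn24 under the series matrix (-0.26). Hog1 programme genes stood closer together, at 0.96 ± 0.21, 0.58 ± 0.19, 0.53 ± 0.06 and 0.52 ± 0.10.

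**Figure D1:**
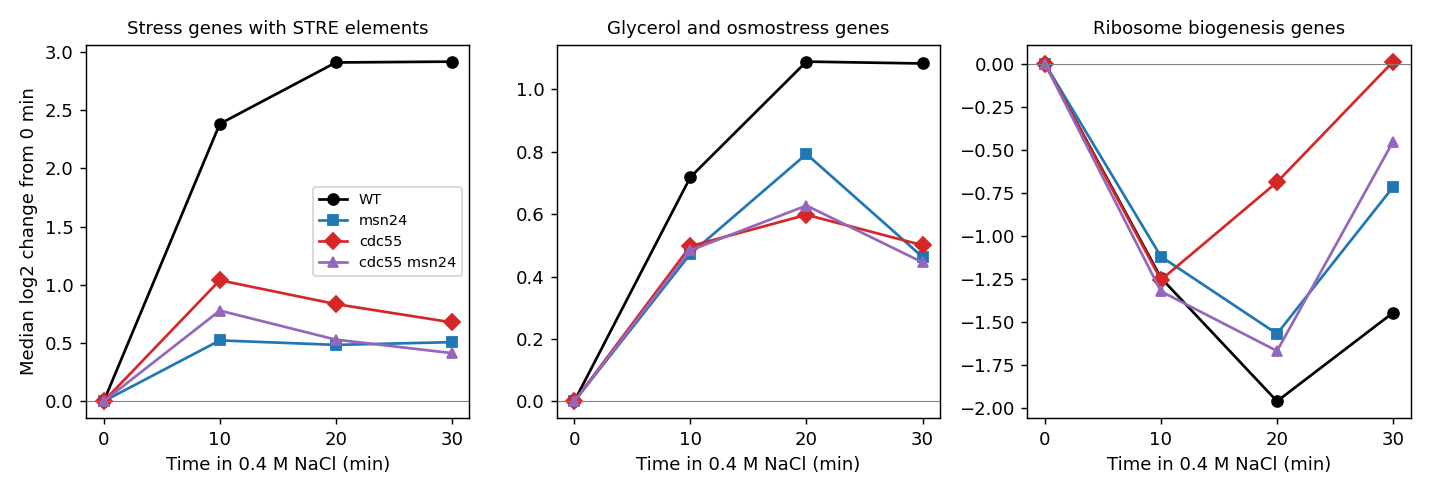
Median log2 change from 0 min against time in salt (min) for the STRE, glycerol and osmostress, and ribosome biogenesis lists, 1 line per strain and 1 sample per point. The STRE median reached 2.92 at 30 min in WT and 0.68, 0.51 and 0.41 in cdc55, msn24 and cdc55 msn24.

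For ribosome biogenesis genes the median change was -1.24, -1.96 and -1.45 at 10, 20 and 30 min in WT, -1.12, -1.57 and -0.72 in msn24, -1.26, -0.69 and 0.01 in cdc55, and -1.32, -1.67 and -0.45 in cdc55 msn24. Counts of genes at least 2-fold from 0 min followed a similar course. In WT 314 genes were higher and 339 lower at 10 min, 544 and 560 at 20 min, and 503 and 415 at 30 min. In cdc55 these counts were 197 and 275, then 173 and 160, then 136 and 83. In msn24 they were 187 and 247, 265 and 398, and 214 and 213, and in cdc55 msn24 251 and 277, 246 and 348, and 189 and 153. Without genes with discordant spots the counts at 30 min were 391 and 366 in WT, 126 and 197 in msn24, 77 and 79 in cdc55, and 117 and 143 in cdc55 msn24. At 20 min in cdc55 they were 115 and 150. With 1 sample per point these courses were not tested.

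**Figure D2:**
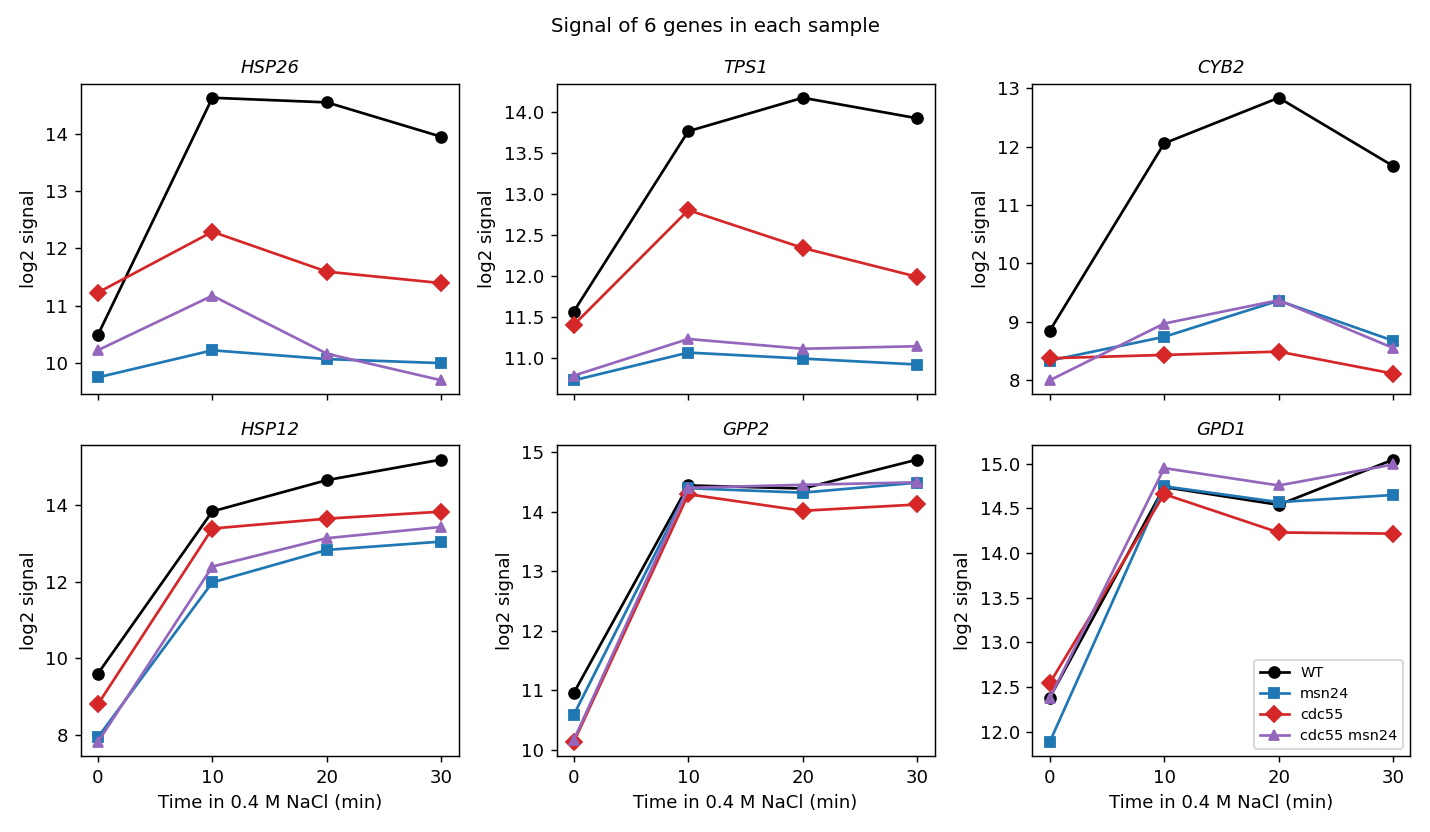
Log2 normalized signal of HSP26, TPS1, CYB2, HSP12, GPP2 and GPD1 against time in salt (min), 1 line per strain and 1 sample per point. HSP26 was 14.9-fold above 0 min in WT as a mean of the salt times and 1.45-fold in cdc55, while HSP12 was 31.3-fold and 28.4-fold above it.

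Between msn24 and WT, 34 of 64 stress genes with STRE elements and 10 of 21 genes of trehalose and glycogen metabolism responded less to salt in msn24, a label that the MSN4 probe does not check. Most of the trehalose and glycogen genes, TSL1, GPH1, GLC3 and TPS1 among them, are also in the STRE list, so these are not 2 separate results. The largest differences between msn24 and WT in the salt response were those of DDR2 (-5.36 ± 0.70, adjusted p = 0.00403), the aldehyde dehydrogenase gene ALD3 (-4.80 ± 0.39, adjusted p = 0.000388), and the 6-phosphogluconolactonase gene SOL4 (-4.46, adjusted p = 0.000388). The dubious reading frame YBR116C (-4.54), which overlaps TKL2, was among them too, as were BDH2 (-4.30), FMP16 (-4.10), the phosphoglucomutase gene PGM2 (-3.87), EGO4 (-3.85) and DCS2 (-3.78). The transketolase gene TKL2 also passed (adjusted p = 0.00729), but it was not above background at 0 min in either strain, so the size of its difference and its rank are not known. All 10 were lower at 3 of 3 salt times. SOL4 was 30.7-fold above 0 min in WT and 1.39-fold in msn24, and ALD3 32.9-fold against 1.18-fold. Of the 64 STRE genes 34 responded less (51 adjusted over the list alone), by a list median of -1.84 (camera adjusted p = 4.75e-60, adjusted p = 0.116 with an estimated correlation). Of 21 trehalose and glycogen genes 10 responded less (15 adjusted over the list alone), among them TSL1 (-3.10), the glycogen phosphorylase gene GPH1 (-3.04), the branching enzyme gene GLC3 (-2.59) and TPS1 (-2.13), with a median of -1.45 (adjusted p = 1.46e-21, adjusted p = 0.0675 with an estimated correlation).

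CTT1 (-1.87, adjusted p = 0.0346) and HSP26 (-3.55, adjusted p = 0.000388) also responded less in msn24. HSP12 (-0.28, adjusted p = 0.78), GPD1 (0.38, adjusted p = 0.667), STL1 (0.07, adjusted p = 0.968), ENA1 (0.03, adjusted p = 0.983) and GRE2 (-0.43, adjusted p = 0.807) did not pass. Oxidative stress genes had 4 of 29 lower (7 adjusted over the list alone), such as the glutaredoxin gene GRX2 (-1.56), with a median of -0.38 (camera adjusted p = 7.12e-08, adjusted p = 0.437 with an estimated correlation). Respiration genes had 2 of 47 lower (2 adjusted over the list alone), including the lactate dehydrogenase gene CYB2 (-2.75), with a median of -0.32 (adjusted p = 1.36e-08, adjusted p = 0.437 with an estimated correlation). FSH1 (1.22 ± 0.25, adjusted p = 0.0382) and the mannosyltransferase gene KTR2 (0.78 ± 0.16, adjusted p = 0.0365) responded more, each at 3 of 3 times. Camera called 15 of the 24 lists, and 0 of them held with an estimated correlation. Among the rest, ribosome biogenesis genes stood at 0.48 (adjusted p = 3.01e-09, adjusted p = 0.584 with an estimated correlation). The Hog1 programme stood at -0.22 with 2 of 33 lower (5 adjusted over the list alone, adjusted p = 0.0122, adjusted p = 0.54 with an estimated correlation) and turned to 0.09 with quantile scaling. In limma the genes called for the msn24 effect on the salt response were 2 higher and 90 lower, with 524 at an unadjusted p under 0.05. Without 10 min 227 genes passed, without 20 min 14 and without 30 min 38, and the split was 31 higher and 31 lower with processed signals and 43 and 42 with the series matrix. The msn24 and WT samples also differ in mating type.

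In cdc55, 11 of 64 stress genes with STRE elements and 2 of 21 genes of trehalose and glycogen metabolism, lists that share members, responded less to salt than in WT. Among the lowest were RPL12B (-3.38, discordant spots), CYB2 (-3.37 ± 0.31, adjusted p = 0.000838), HSP26 (-3.36 ± 0.40, adjusted p = 0.00366), and HXT5 (-3.03 ± 0.43, adjusted p = 0.01). Next came the butanediol dehydrogenase homologue BDH2 (-2.94), SOL4 (-2.90), MSC1 (-2.81), the carboxypeptidase inhibitor gene TFS1 (-2.73) and YPL247C (-2.72, discordant spots), each lower at 3 of 3 salt times. CYB2 was 10.2-fold above 0 min in WT and at -0.03 log2 in cdc55, HSP26 14.9-fold against 1.45-fold, and TFS1 12.1-fold against 1.83-fold. HXT5 was at least 26.6-fold above 0 min in WT and at least 3.26-fold in cdc55. TKL2 had a fitted difference of -4.14 ± 0.73 (adjusted p = 0.0278), with at least 34.1-fold in WT and at least 1.94-fold in cdc55. Neither gene was above background at 0 min in these strains and BDH2 was not in cdc55, so the sizes of their differences and their ranks are not known. Genes that responded more were RPS1B (1.25 ± 0.21, adjusted p = 0.0183), whose log2 change was -1.23 in WT and 0.03 in cdc55, the phenylalanyl-tRNA synthetase gene FRS1 (1.20, discordant spots), and the replication origin gene ORC1 (0.95 ± 0.19, adjusted p = 0.0455), each at 3 of 3 times. The glycerophosphoinositol permease gene GIT1 passed too (adjusted p = 0.0147), but it was above background in 5 of 16 samples, so the size of its difference is not known.

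The STRE list had 11 of 64 members with a lower response in cdc55 (50 adjusted over the list alone) and a median of -1.61, or -1.71 without genes with discordant spots (camera adjusted p = 7.77e-29, adjusted p = 0.437 with an estimated correlation). Trehalose and glycogen genes had 2 of 21 lower (12 adjusted over the list alone), among them GLC3 (-2.32, adjusted p = 0.0147), with a median of -1.23 (adjusted p = 4.56e-11, adjusted p = 0.351 with an estimated correlation). The Hog1 programme had 1 of 33 lower (5 adjusted over the list alone), HXT5, with a median of -0.42 (adjusted p = 0.00234, adjusted p = 0.437 with an estimated correlation). Ribosome biogenesis genes had a median of 0.99 (adjusted p = 5.41e-17, adjusted p = 0.437 with an estimated correlation), with no single member past the threshold in limma, over all genes or adjusted over the list alone (adjusted p = 0.268 with fry). Ribosomal protein genes had a median of 0.40, with 1 higher and 2 lower (5 and 2 adjusted over the list alone, adjusted p = 5.11e-14 with camera, adjusted p = 0.437 with an estimated correlation). Iron uptake genes had a median of -0.32 (adjusted p = 0.0149, adjusted p = 0.437 with an estimated correlation), with 0 lower in limma and 1 lower adjusted over the list alone. Hexose transporters stood at -0.47, with 1 of 14 lower (1 adjusted over the list alone, adjusted p = 0.0411 with camera, adjusted p = 0.437 with an estimated correlation), and at 0.29 with 75th percentile scaling.

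Several stress genes did not pass in cdc55. DDR2 stood at -3.94 (adjusted p = 0.0734), TPS1 at -1.42 (adjusted p = 0.108), ALD3 at -1.33 (adjusted p = 0.229) and CTT1 at -1.23 (adjusted p = 0.238). Also short of the threshold were STL1 at -1.06 (adjusted p = 0.297), GRE2 at -0.93 (adjusted p = 0.426), ENA1 at -0.76 (adjusted p = 0.317), GPD1 at -0.57 (adjusted p = 0.355), HSP12 at -0.14 (adjusted p = 0.856), CLB2 at 0.12 (adjusted p = 0.872) and CLN2 at 0.20 (adjusted p = 0.702). The genes called for the cdc55 effect on the salt response were 4 higher and 45 lower, of which 1 and 23 had discordant spots, with 881 at an unadjusted p under 0.05. Without 10 min 964 genes passed, without 20 min 3 and without 30 min 13. Without the genes with discordant spots 2 were higher and 19 lower. Scaling on the 75th percentile moved the median of all genes to 0.42 and gave 1357 higher and 93 lower, and the series matrix moved that median to -0.19. Of the genes with a lower response, 24 were shared with the 90 of msn24, against 0.741 for independent lists. The covariance of the 2 effects over 5468 genes was 0.185 against 0.0357 in 100 simulations with no effect, and their correlation 0.765 against 0.399. Both comparisons use the WT samples, which cannot be divided between them and add to such an overlap. The simulations gave the 0 min samples the spread of the salt samples, though the 0 min arrays had the most discordant spots. They may understate what the shared WT 0 min sample adds, so the excess does not show that the effects are alike.

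Between cdc55 msn24 and msn24, no gene of the STRE list passed for the cdc55 effect on the salt response (0 in limma and 0 adjusted over the list alone). The list stood at 0.02 (camera adjusted p = 0.501, adjusted p = 0.946 with fry), and at 0.03 without discordant genes, with values of -0.30 under processed signals, -0.18 under quantile scaling, -0.61 under the series matrix, -0.15 under background-subtracted signals and 0.63 under 75th percentile scaling. HSP12 stood at 0.49, CTT1 at 1.21, TPS1 at 0.11 and GPD1 at -0.25 (adjusted p = 0.848 to 0.999). The genes called for the cdc55 effect on the salt response without Msn2 and Msn4 were 0 higher and 11 lower, among them the ADP/ATP carrier gene PET9 (-2.88), the sterol synthesis gene HMG1 (-2.82), the unfolded protein response factor HAC1 (-2.28), and the chitin precursor gene GFA1 (-2.14). Others were RFA2 (-2.09), MXR2 (-2.08), RPS18B (-2.06), GTR2 (-2.02), CSH1 (-1.85) and MSL5 (-1.50), with adjusted p from 0.000834 to 0.0159 and each lower at 3 of 3 times. All 11 had discordant spots on the 0 min array of WT and msn24. Without the genes with discordant spots 0 passed in limma, with 190 at an unadjusted p under 0.05. With them 283 had an unadjusted p under 0.05, fry called 0 of the lists, and 17, 0 (113 unadjusted) and 7 genes passed without 10, 20 and 30 min. Scaling on the 75th percentile moved the median of all genes to 0.35 and gave 1099 higher and 21 lower, and the series matrix moved it to -0.21.

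**Figure D3:**
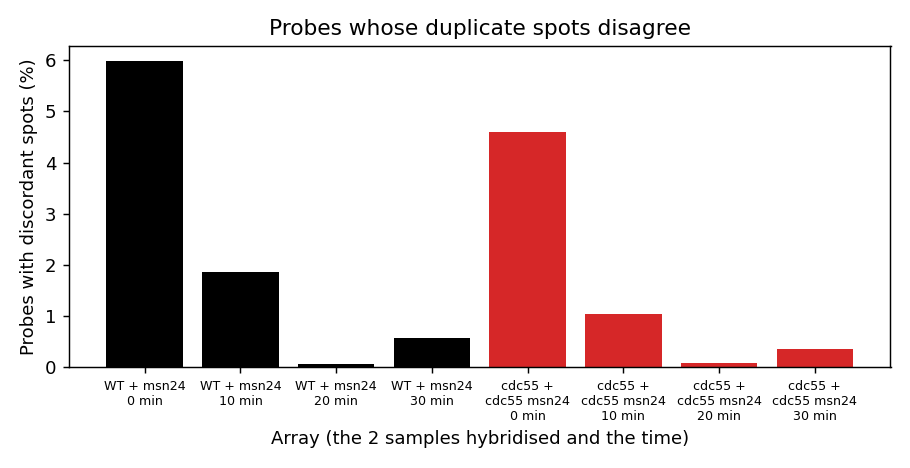
Percent of the 6256 gene probes whose spots disagreed by over 2-fold in both dyes, per array, by the pair of strains and the time (min). The 0 min arrays had 5.98% and 4.59%, and the others 0.0639% to 1.85%.

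Camera called 7 of the lists in that comparison. Ribosomal protein genes stood at 0.20 (adjusted p = 1.42e-05, adjusted p = 0.865 with an estimated correlation), amino acid synthesis genes at 0.24 (adjusted p = 0.000236, adjusted p = 0.865 with an estimated correlation) and respiration genes at 0.18 (adjusted p = 0.0021, adjusted p = 0.865 with an estimated correlation). Cell wall integrity genes stood at -0.33, with 1 of 35 lower (2 adjusted over the list alone, adjusted p = 1.42e-05 with camera, adjusted p = 0.865 with an estimated correlation).

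The effect of cdc55 on the salt response differed between strains with and without Msn2 and Msn4 in a direct test of the difference, which 9 genes passed, the deleted MSN2 among them. Those strains also differ in mating type and dye, which the test does not separate from Msn2 and Msn4. CYB2 (-3.75 ± 0.35, adjusted p = 0.00149), BDH2 (-3.67), HSP26 (-3.14), HXT5 (-3.12), the cytochrome c gene CYC7 (-3.06), RPL12B (-2.79, discordant spots), and GLC3 (-2.63) had lower values with Msn2 and Msn4 present, with adjusted p from 0.000416 to 0.0393. FRS1 (2.15, discordant spots, adjusted p = 0.00229) had a higher one, and all held at 3 of 3 times. HXT5 was not above background at 0 min in WT and cdc55, and BDH2 was not in cdc55, so the sizes of their differences are not known. MSN2 passed with -2.33, which carries no measured difference, since its probe was not above background in any msn24 or cdc55 msn24 sample. STRE genes had 3 of 64 lower (48 adjusted over the list alone) and a median of -1.75 (camera adjusted p = 1.92e-37, adjusted p = 0.317 with an estimated correlation), and trehalose and glycogen genes 1 of 21 (9 adjusted over the list alone) and -1.24 (adjusted p = 3.05e-10, adjusted p = 0.317 with an estimated correlation). The part of the STRE response that goes with the msn24 label was 1.88 ± 0.36 in WT minus msn24 and 0.12 ± 0.03 in cdc55 minus cdc55 msn24, where the CDC55 probe does not check the label. Nor does the MSN4 probe check the msn24 label. For trehalose and glycogen genes, most of them also STRE genes, this part was 1.52 ± 0.43 and 0.24 ± 0.12, and for the Hog1 programme 0.16 ± 0.04 and -0.03 ± 0.03. For ribosome biogenesis genes it turned sign, from -0.44 ± 0.24 in WT minus msn24 to 0.53 ± 0.46 in cdc55 minus cdc55 msn24. The median of that list in the test of the difference was 0.97. The genes called for the difference of the cdc55 effects with and without Msn2 and Msn4 were 1 higher and 8 lower, with 507 at an unadjusted p under 0.05. Without 10, 20 and 30 min 150, 2 and 2 genes passed, and the higher and lower counts were 1 and 1 with processed signals, 1 and 2 with quantile scaling, 3 and 1 with the series matrix, and 1 and 2 with background-subtracted signals.

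Over all times, 91 of 106 ribosome biogenesis genes were higher in cdc55 than in WT (adjusted p = 0.664 with an estimated correlation) and 41 of 47 respiration genes lower (adjusted p = 0.563 with an estimated correlation). So were 47 of 64 STRE genes (adjusted p = 0.664 with an estimated correlation), though their median was -0.05 at 0 min. TIR1, a cell wall mannoprotein of cold and anaerobic cells, was 4.95 ± 0.13 log2 higher (adjusted p = 8.13e-11) and ANB1, the hypoxic form of the translation factor eIF5A, 4.72 ± 0.13 (adjusted p = 8.13e-11). The purine synthesis genes ADE57 (3.07, adjusted p = 3.86e-06), ADE2 (2.94, discordant spots) and ADE17 (2.94, adjusted p = 3.37e-05), and the salvage gene HPT1 (1.98, discordant spots) followed, then INA1 (1.94), the nucleolar gene NSR1 (1.88), SYO1 (1.77) and the hypoxic ADP/ATP carrier gene AAC3 (1.77). The lowest were the cytochrome c genes CYC1 (-3.49, discordant spots) and CYC7 (-3.24, adjusted p = 0.000739), DDR2 (-3.20, adjusted p = 0.012), and the heme oxygenase gene HMX1 (-3.18, adjusted p = 3.44e-05). They were followed by the hexose transporter gene HXT7 (-3.08), EGO4 (-3.06), CYB2 (-3.00), FET3 (-2.88), the hexokinase gene HXK1 (-2.82) and GPH1 (-2.60). Each of these 20 differed the same way at 4 of 4 times. The times of a strain stand in for repeats, so these p-values hold no spread between cultures of the same strain. Of the anchor genes HSP12 (-0.90, adjusted p = 0.000492), CTT1 (-1.19, adjusted p = 0.0133) and TPS1 (-1.23, adjusted p = 0.0168) were lower, and GPD1 (-0.26, adjusted p = 0.226) and STL1 (-0.58, adjusted p = 0.182) did not pass.

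Respiration genes were lower in cdc55, 41 of 47 with none higher (42 adjusted over the list alone), including NDI1 (-1.70) and RIP1 (-1.72, discordant spots), with a median of -0.90 (camera adjusted p = 1e-15, adjusted p = 0.563 with an estimated correlation). Ribosome biogenesis genes were higher, 91 of 106 (93 adjusted over the list alone), with a median of 1.03 (adjusted p = 4.97e-18, adjusted p = 0.664 with an estimated correlation) and 0.26 at 0 min. Ribosomal protein genes had 95 of 131 higher (98 adjusted over the list alone) and a median of 0.42 (adjusted p = 1.28e-17, adjusted p = 0.65 with an estimated correlation). STRE genes had 47 of 64 lower (48 adjusted over the list alone), with a median of -1.25 over all times (adjusted p = 1.12e-08, adjusted p = 0.664 with an estimated correlation) and -0.05 at 0 min. Iron uptake genes had 17 of 25 lower and 3 higher (17 and 3 adjusted over the list alone), such as ARN1 (-1.51) and CCC2 (-1.15), with a median of -0.56 (adjusted p = 0.000127, adjusted p = 0.563 with an estimated correlation). Oxidative stress genes had 17 of 29 lower and 2 higher (17 and 2 adjusted over the list alone), among them MCR1 (-2.27), the sulfiredoxin gene SRX1 (-1.67) and the superoxide dismutase gene SOD1 (-1.60), with a median of -0.53 (adjusted p = 0.00135, adjusted p = 0.664 with an estimated correlation). In the amino acid synthesis list 24 of 60 were higher and 11 lower (24 and 12 adjusted over the list alone), with a median of 0.26 (adjusted p = 0.0264, adjusted p = 0.777 with an estimated correlation). Its 4 highest members were the purine synthesis genes ADE17, ADE1 (1.63, discordant spots), ADE4 and ADE13 (1.48).

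In limma the genes called for cdc55 against WT over all times were 1328 higher and 1474 lower, with 3146 at an unadjusted p under 0.05. Without 20 min 1684 genes passed and without 30 min 1810, and the split was 558 higher and 945 lower with 75th percentile scaling and 485 and 948 with the series matrix. The cdc55 and WT levels come from different arrays with the same dye.

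**Figure D4:**
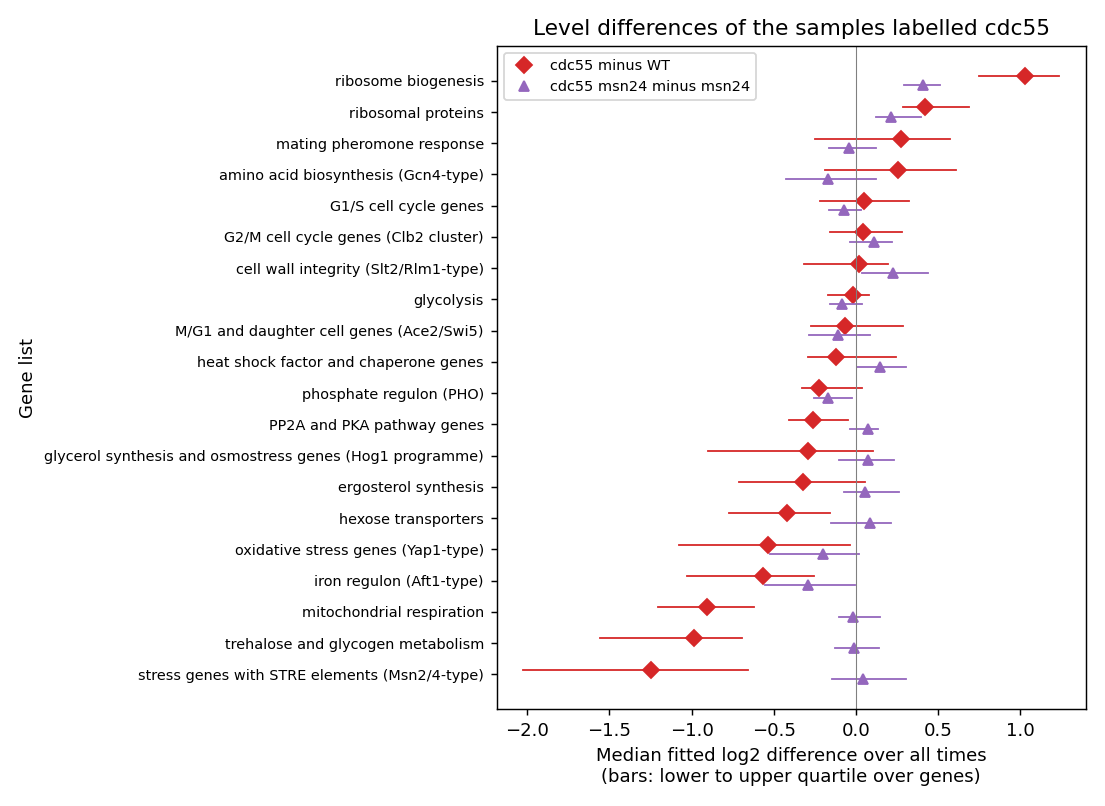
Median log2 level difference over all times of the gene lists with at least 14 members (x axis), for cdc55 minus WT (diamonds) and cdc55 msn24 minus msn24 (triangles), with quartile bars over the list members. Respiration genes lie at -0.90 and -0.02, STRE genes at -1.25 and 0.04 (-0.07 with 75th percentile scaling and -0.05 with the series matrix), and ribosome biogenesis genes at 1.03 and 0.41.

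Between cdc55 msn24 and msn24 the levels differed for fewer genes. Here too the times of a strain stood in for repeats. ARG1 of arginine synthesis was lowest (-2.60 ± 0.25, adjusted p = 0.000121), followed by FET3 (-1.97, adjusted p = 0.00211), YNL134C (-1.84) and the drug exporter gene ATR1 (-1.67, adjusted p = 0.00115). The others were the glutathione transferase gene GTT2 (-1.66, adjusted p = 0.000121), the acid phosphatase gene PHO5 (-1.62, adjusted p = 0.000108), YFL057C (-1.36), YLR159W (-1.34), YLR156W (-1.31) and the cyclophilin gene CPR5 (-1.30, adjusted p = 3.91e-05). The highest were TMA10 (1.77, adjusted p = 0.0417), ADE2 (1.45, discordant spots), RPS18B (1.22, discordant spots) and the glucose transporter gene HXT2 (1.12, adjusted p = 0.00214). After them came the leucine gene LEU1 (1.05), PRM5 (1.04), TIR1 (1.00 ± 0.13, adjusted p = 0.00126), the ubiquitin gene UBI4 (0.95), YGR109W-A (0.85) and the helicase gene DBP2 (0.84). All 20 differed the same way at 4 of 4 times. Together, genes called for cdc55 msn24 against msn24 over all times were 78 higher and 123 lower, with 1095 at an unadjusted p under 0.05. Without 10, 20 and 30 min 82, 43 and 62 genes passed, and the split was 49 higher and 160 lower with quantile scaling, 3 and 42 with 75th percentile scaling and 25 and 192 with the series matrix.

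Of 25 iron uptake genes 5 were lower in cdc55 msn24 than in msn24 (6 adjusted over the list alone), among them FIT3 (-0.95) and FTR1 (-0.86), with a median of -0.29 (camera adjusted p = 3.57e-06, adjusted p = 0.528 with an estimated correlation). Amino acid synthesis genes had 11 of 60 lower and 1 higher (19 and 3 adjusted over the list alone), such as LYS9 (-1.12) and ARG7 (-0.96), with a median of -0.17 (adjusted p = 6.91e-07, adjusted p = 0.727 with an estimated correlation). Oxidative stress genes had 5 of 29 lower and 1 higher (9 and 2 adjusted over the list alone), such as the thioredoxin gene TRX1 (-1.16), with a median of -0.20 (adjusted p = 2.51e-05, adjusted p = 0.727 with an estimated correlation). Ribosomal protein genes had 13 of 131 higher (34 higher and 1 lower adjusted over the list alone) and a median of 0.21 (adjusted p = 1.23e-14, adjusted p = 0.727 with an estimated correlation). Ribosome biogenesis genes had 1 of 106 higher (1 adjusted over the list alone) and a median of 0.41 (adjusted p = 1.1e-10, adjusted p = 0.785 with an estimated correlation), and cell wall integrity genes 5 of 35 (9 higher and 1 lower adjusted over the list alone) and 0.23 (adjusted p = 0.00353, adjusted p = 0.727 with an estimated correlation). STRE genes stood at 0.04 (adjusted p = 0.573), or -0.07 with 75th percentile scaling and -0.05 with the series matrix, and respiration genes at -0.02 (adjusted p = 0.759).

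Before salt, few genes differed between strains by 2-fold or more. In cdc55 80 were higher and 59 lower than in WT at 0 min, led by TIR1 (38.1-fold), ANB1 (30.8-fold), RPL12B (3.62 log2, discordant spots), ADE17 (3.29) and ADE57 (3.03). The lowest were CYC1 (-4.64, discordant spots), CYT1 (-2.22), the flavohemoglobin gene YHB1 (-2.16), HMX1 (-2.12) and HXK1 (-2.03). In cdc55 msn24 52 were higher and 64 lower than in msn24. The 5 highest, HMG1 (2.84), RPS18B (2.77), PET9 (2.70), GFA1 (2.55) and HAC1 (2.35), had discordant spots, and ARG1 (-3.25), the ammonium transporter gene MEP2 (-2.58), GTT2 (-2.14), AGP1 (-2.08) and ATR1 (-2.06) were lowest. In msn24 30 were higher and 23 lower than in WT. This sets Cy5 against Cy3, so a gene-specific dye bias does not cancel. All genes named here are ranked among those well above background in both samples. The highest in msn24 were the mating-type genes HMLALPHA1 (3.43) and MATALPHA1 (3.30), AFB1 (3.33), the dubious reading frame YCR041W (3.33) and RPL12B (2.82, discordant spots). MF(ALPHA)1 differed more (log2 signal 13.95 against 8.45) but was not above background in WT. The lowest there were HXK1 (-3.44), STE6 (-2.79), HXT7 (-2.41), STF2 (-2.05) and the glucokinase gene GLK1 (-2.01). These single-array differences were not tested. Chromosome medians of the strain differences averaged -0.09 to 0.06 over the times, against 1 for a gain from 1 copy to 2.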

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

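The test of the difference in level effects, its swaps of times, and the tests weighing the STRE response and the level differences, except that of a generally weaker response on genes raised in cdc55 msn24, were chosen only after the result was seen.

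The effect of cdc55 on the salt response was tested for a difference between strains with and without Msn2 and Msn4, which 9 genes passed, 1 higher and 8 lower with the deleted MSN2 among them (limma, 3 of 3 times each). Mating type and dye differ between those strains too and were not separated from Msn2 and Msn4. Lower were CYB2 (-3.75), BDH2 (-3.67), HSP26 (-3.14), HXT5 (-3.12), CYC7 (-3.06), RPL12B (-2.79, discordant spots), GLC3 (-2.63) and MSN2 (-2.33), and FRS1 (2.15, discordant spots) was higher. HXT5 was not above background at 0 min in WT and cdc55, nor BDH2 in cdc55, so the sizes of their differences are not known. The MSN2 value is no measured difference, as it rests mostly on the 2 strains where its probe was not above background, with changes of -0.75 in msn24 and 0.96 in cdc55 msn24, and stood at 0.37 with quantile scaling. CYB2, HSP26, HXT5, BDH2, CYC7, RPL12B and GLC3 also passed as lower for the salt response of cdc55 against WT. That comparison is a part of the tested difference, so this is no separate support.

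The lower salt response of STRE genes in cdc55 was weighed against 3 explanations, of which signal lost in duplicate spots does not account for it since the list median was -1.71 without genes with discordant spots. A generally weaker response of the cdc55 culture would lower other salt genes as much. The ratio of cdc55 to WT exceeded that of STRE genes (0.318 ± 0.106) by 0.503 ± 0.028 for 166 other genes raised 2-fold in cdc55 msn24 (0.383 for the 108 without discordant spots). That strain shares its arrays with cdc55, so errors of an array could raise this ratio. The excess was 0.323 ± 0.0445 for 156 other genes raised 2-fold in msn24, which shares its arrays with WT and none with cdc55. Such errors would lower the ratio there. A partly weaker response stays open, as the ratio of these 156 genes was 0.641 ± 0.146, though shared arrays may have lowered it. The medians were also nearer 0 in cdc55 than in WT for the Hog1 programme (0.53 and 0.96) and ribosome biogenesis genes (-0.64 and -1.55). A raised 0 min level would need a difference near the loss of 1.89, but the list stood at -0.0502 at 0 min, so lower action of Msn2 and Msn4 in cdc55, a label that the CDC55 probe does not check, may be the source, or another difference between the cultures.

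The level effects of cdc55 also differed between the backgrounds. These backgrounds also differ in mating type and in dye (Cy3 or Cy5), so the difference cannot be assigned to Msn2 and Msn4. A level here averages 0, 10, 20 and 30 min and so includes the salt response. For STRE genes, whose median stood at -0.05 at 0 min in cdc55 minus WT, it is not a result separate from that response. The genes called for the difference of the cdc55 level effects with and without Msn2 and Msn4 were 736 higher and 1125 lower with both present (limma, 2537 at an unadjusted p under 0.05). The counts without 10, 20 and 30 min were 770, 539 and 676. ANB1 (4.10 ± 0.15, adjusted p = 3.79e-09), TIR1 (3.95 ± 0.15, adjusted p = 4.06e-09), ARG1 (2.92) and ADE57 (2.69) were highest, and CYC1 (-4.08, discordant spots), TMA10 (-3.83), CYC7 (-3.82) and HXT7 (-3.40) lowest, each at 4 of 4 times. Respiration genes had 40 of 47 lower (40 adjusted over the list alone), with a median of -0.95 (camera adjusted p = 2.71e-18, adjusted p = 0.491 with an estimated correlation). STRE genes had 42 of 64 lower (50 adjusted over the list alone), with a median of -1.32 (adjusted p = 4.72e-11, adjusted p = 0.595 with an estimated correlation).

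The level differences between cdc55 and WT were weighed against 3 explanations. Loss of CDC55 alone, whatever the rest of the strain, would lower respiration genes in both backgrounds, but their median was -0.0168 in cdc55 msn24 minus msn24 against -0.90 in cdc55 minus WT. This covers respiration genes only. Of the genes called in cdc55 msn24 against msn24, 50 of 78 higher and 67 of 123 lower were also called that way in cdc55 against WT. Independent lists would share 18.9 and 33.2, though shared arrays add to such an overlap. The medians of ribosome biogenesis and iron uptake genes also went the same way in both, so loss of CDC55 alone stays open for such genes. Lower heme- and oxygen-dependent transcription in the cdc55 culture stays open. The median of hypoxic genes lay 1.20 above that of heme-activated genes (0.22 and -0.98), mostly through the heme-activated genes. The set criterion, a camera p under 0.05 for both lists in opposite directions, was not met. Those lists were also drawn up after the values were seen, so the gap cannot decide. Dim spots and Cy3 haze do not account for the 1367 brightest genes, where 99.7% of the 669 called differed by more than the whole Cy3 background could add, and stay open for the dimmer ones, where 68.4% of 645, 17.5% of 702 and for the 1367 dimmest 1.78% of 786 did. This bound sets raw background against normalized signals, so it is approximate. Its median was 0.112 log2 for the brightest genes, which nearly every called difference there exceeds. An effect of CDC55 that needs Msn2 and Msn4, an unlabelled difference of the cdc55 strain, and growth state stay open with 1 culture per strain. Mating type and dye stay open too, as they differ between the backgrounds along with Msn2 and Msn4. Levels over all times also include the differences in salt response, which these tests did not separate.

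Other splits of the samples were run for each count. For the genes called in the salt response over the strains the real count was the largest of 100 splits (2608 against at most 5 in the others). These splits moved the times within each strain alone, which broke the array that 2 strains share at each time. They therefore do not exclude chance for samples paired by array. The real count was the largest of 35 splits for cdc55 against WT over all times (2802 against 317) and for cdc55 msn24 against msn24 over all times (201 against 1), but most of these splits mix the times that match the samples. Only 8 keep the times matched, too few for a share under 0.05, and the highest other count among them was 0 in both comparisons. For the rest the 8 swaps are too few as well. The real count and the highest other were 49 and 1597 for the cdc55 effect on the salt response, 92 and 801 for the msn24 effect, 11 and 134 for the cdc55 effect without Msn2 and Msn4, 9 and 1126 for the difference of these effects, and 1861 and 0 for the difference of the level effects. Apart from the difference of the level effects, 2 of 8 swaps, the real one included, called at least as many genes as the real one. The larger counts belong only to the swap of all salt times, which exchanges the strains' levels and so points to level differences between the strains as a structure of the samples.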

How the results depend on the processing

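Chosen after seeing the data were background-subtracted signals, the lower discordant spot dropped, discordant genes left out, and every refit of the difference in level effects. Over 419 refits, each of the 24 genes named for salt kept its direction and stayed past the threshold (adjusted p from 8.48e-12 to 0.0186). For the msn24 effect 139 of 165 refits did so and 26 fell short. For the cdc55 effect 147 of 203 did, 54 fell short and 2 reversed, and for cdc55 levels against WT 269 of 272 did. Without Msn2 and Msn4, 97 of 140 did for the salt response, with 16 reversed, and 236 of 275 for levels. For the difference of the cdc55 effects 73 of 120 did, 46 fell short and 1 reversed, and for that of the level effects 262 of 274 did. Of the counts and STRE medians under an alternative, 63 lay outside the bound (1.5 times for counts, 1 SD for medians) and are given by setting. Signal over background limits dim genes in Cy3, where 52.8% to 75.7% of spots stood well above it. Where nothing else is said the cause was not tested.

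With processed signals there were 29 genes called for the cdc55 effect on the salt response, 33 genes called for the cdc55 effect on the salt response without Msn2 and Msn4, and 2 genes called for the difference of the cdc55 effects with and without Msn2 and Msn4. There were 1846 genes called for cdc55 against WT over all times and 675 genes called for the difference of the cdc55 level effects with and without Msn2 and Msn4. STRE medians were 3.18 in WT, 1.24 in msn24, 1.22 in cdc55 and 0.84 in cdc55 msn24, and GTR2 reversed (0.128) in the comparison without Msn2 and Msn4. With quantile scaling there were 41 genes called for the msn24 effect on the salt response and 3 for the difference of the cdc55 effects, the STRE median was 0.71 in msn24, and MSN2 reversed in the difference of the cdc55 effects (0.37). With 75th percentile scaling 1359 were genes called in the salt response over the strains, 1450 passed for the cdc55 effect, 1120 for that without Msn2 and Msn4, and 1503 for cdc55 against WT. The genes called for cdc55 msn24 against msn24 over all times were 45, and STRE medians were 0.35 in msn24, 1.09 in cdc55 and 0.88 in cdc55 msn24. With the series matrix 28 passed for the cdc55 effect, 32 without Msn2 and Msn4, 4 for the difference of these, 1433 for cdc55 against WT and 675 for the difference in level effects, and STRE medians were 1.07 in msn24 and 0.37 in cdc55 msn24. The matrix and the 75th percentile move the median of all genes, by construction.

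With only genes well above background in all samples, so with fewer genes tested, there were 1463 genes called for cdc55 against WT over all times and 1007 genes called for the difference of the cdc55 level effects with and without Msn2 and Msn4, and the STRE median was 0.55 in msn24. With background-subtracted signals there were 17 genes called for the cdc55 effect on the salt response without Msn2 and Msn4, 3 for the difference of the cdc55 effects, 334 genes called for cdc55 msn24 against msn24 over all times and 984 for the difference in level effects, the STRE median was 0.77 in msn24, and GTR2 reversed (0.147). Without an array block 47 passed for the msn24 effect, 3 for the difference of the cdc55 effects and 1064 for the difference in level effects. With discordant genes left out 21 passed for the cdc55 effect and 0 without Msn2 and Msn4 (limma, 190 unadjusted). With the lower discordant spot dropped 6 passed without Msn2 and Msn4, 1 of them among the 11 called without this step, and PET9 (0.00844), HAC1 (0.25), GFA1 (0.000552), RFA2 (0.0908), MXR2 (0.18), RPS18B (0.19) and MSL5 (0.0563) reversed, since the low spots on which these calls rested were gone.

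Leaving out a time means fewer samples. The range over the times was 3 to 964 for genes called for the cdc55 effect on the salt response, 14 to 227 for genes called for the msn24 effect on the salt response, 0 to 17 for genes called for the cdc55 effect on the salt response without Msn2 and Msn4 (limma, 113 unadjusted at the lowest), and 2 to 150 for genes called for the difference of the cdc55 effects with and without Msn2 and Msn4. It was 1684 to 2512 for genes called for cdc55 against WT over all times, 43 to 82 for genes called for cdc55 msn24 against msn24 over all times and 539 to 770 for genes called for the difference of the cdc55 level effects with and without Msn2 and Msn4. With levels under salt only, which drop the 0 min samples and so fit a difference in level and not in the salt response, 2959 passed for the cdc55 effect and 139 without Msn2 and Msn4. By construction a sign that turns there does not reverse the salt effect. These signs are counted above as 2 reversals for the cdc55 effect and 7 of the 16 without Msn2 and Msn4. There GIT1 (-0.000917) and RPL12B (0.24) turned for the cdc55 effect, and HMG1 (0.028), HAC1 (0.0668), GFA1 (0.40), RPS18B (0.70), GTR2 (0.12), CSH1 (0.0497) and MSL5 (0.19) without Msn2 and Msn4.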

Other observations

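All tests of this part were chosen only after the result was seen. In the list of 15 hypoxic genes 6 were higher and 3 lower in cdc55 than in WT, and their median was 0.22 there and 0.01 in cdc55 msn24 minus msn24. Of 18 heme-activated genes 16 were lower in cdc55 and none higher, with a median of -0.98 against -0.05 in cdc55 msn24 minus msn24. Of 11 purine synthesis genes 7 were higher and 2 lower in cdc55, with a median of 0.48, while in cdc55 msn24 3 were lower than in msn24 and the median was -0.47.

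Iron uptake genes stood at 0.51, 0.43 and 0.38 in WT, msn24 and cdc55 msn24 as mean list medians of the salt times, and at -0.03 in cdc55, where the sign turned with quantile and 75th percentile scaling and with background-subtracted signals. Phosphate genes stood at -0.66, -0.73, -0.34 and -0.43 in WT, msn24, cdc55 and cdc55 msn24. These strain values were not tested.

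The 11 genes with a lower salt response in cdc55 msn24 than in msn24 were weighed against the loss of signal in a spot. Of them 100% had discordant spots on the 0 min array of WT and msn24, against 6.82% of all genes. With the lower spot dropped their median difference was 0.00844 against -2.08 and 7 of the 11 reversed, which argues against an effect of CDC55 on those 7. It stays open for the other 4, of which 1 still passed. Spots lost on that array are a likely source of most of this pattern, and other genes with discordant spots could carry the same error. PET9, HMG1, HAC1, GFA1, RFA2, MXR2, RPS18B, GTR2, CSH1 and MSL5 were also called lower for the salt response of cdc55 against WT. That comparison uses the same 0 min array, so their calls there may come from the same lost spots.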
